A study of Rattus norvegicus with 52 samples.

How the data were processed

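Total RNA of 1 kidney from each of 26 male rats was hybridised, per the labels, as biotin-labelled cRNA to an Affymetrix RAE230A and an RAE230B chip, and the strain, diet and animal of each array were taken from the labels. The deposited values are on a log2 scale, and their near-equal array medians show that the authors had normalized them. The methods of summary and normalization are not given in the sources used here. The tables held 15923 probe sets with values from 4.11 to 14.69 on RAE230A, and 15333 with values from 3.40 to 13.44 on RAE230B. For arrays, their number limits the precision. Each rat was 1 replicate, the labels give no litter or batch, and replicate numbers do not pair rats between groups.

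The 57 control probe sets of each chip were left out of the tests and used for quality measures. Probe sets with a mean below their chip's median (7.51 and 6.38) were left out, and 100 maintenance probe sets present on both chips were tested on RAE230A only, which left 7933 and 7540. Each chip was fitted separately with limma 3.58.1 in R 4.3.3, with the 6 groups as coefficients, an intensity trend in eBayes and 20 residual degrees of freedom. The 13 comparisons were tested two-sided, Benjamini-Hochberg adjustment ran over both chips together, and probe sets with an adjusted p below 0.05 were called, with no limit on fold. The design, the gene lists and the first set of alternatives were fixed before the data were examined. An offset meant for linear values was not run, because the values were already log2.

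Symbols came from the platform annotation and were updated through Entrez identifiers in a table of the GRCr8 assembly, which also gave chromosomes, gene order and spans. No coordinates are printed, since the build behind the files is not known. Of the tested probe sets 11110 had 1 symbol, 274 several and 4089 none, and they stood for 8825 genes. Named genes are the 12 with the largest change each way among called genes for ET3x2 against S and for salt, 8 each way for ET3x1 against S and 4 for other comparisons, by the probe set of smallest p, with Sgk1 and Agt whatever their value where strains or diets are compared, averaged, and for salt within each strain. Genes whose averaged change rested mostly on 1 diet or strain are also given for each apart, which was chosen after their values were seen. From a gene list, the called members with the largest absolute change are named, and where none is called the 2 with the largest moderated statistic. Rtel1's second probe set and Mvd were chosen after their values were seen. For the 24 gene lists the brightest probe set of each gene was used, with camera at a preset correlation of 0.01 and with an estimated correlation. Without a covariate, no camera call held with an estimated correlation in any comparison.

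The fit was tested on simulated data with known changes among 15473 probe sets. For ET3x2 against S it recovered 58.2% of log2 changes of 0.25 and 97.0% of 0.5, with 11 false among 181 calls (6.08%). For salt over the 3 strains it recovered 80.6% and 100%, with 16 false among 203 calls (7.88%). For salt in ET3x2 it recovered 19.4% and 79.1%, and for the difference between the salt responses of ET3x2 and S 8.96% and 52.2%. A list raised by 0.3 was found by camera in 50 of 50 draws, and 3 of 800 tests of unchanged lists were called. The noise of each simulated probe set or gene was drawn independently. The shares of false calls therefore do not show how often limma errs where noise is shared across the probe sets of an array. Nor do the list rates show how often camera errs where the genes of a list are correlated.

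Alternatives were quantile normalization, centring of array medians, no filter, the brightest 25% of probe sets, no intensity trend, adjustment within each chip, array weights, a fit of the compared strains alone, the 3' to 5' Gapdh ratio as a covariate, and leaving out each rat in turn. The mean of all probe sets of a gene was tried for the lists, single probe sets and other limits on adjusted p for the chromosomes, and separate S rats for the overlap of the congenic strains. After the data were seen, covariates from beta-actin (3' to 5' ratio) and from the spike-in controls (bioD minus bioC) were added, as was leaving out 2 pairs of rats. Single quality measures were compared with exact permutation tests, two-sided, and counts of genes with Fisher's exact test, two-sided.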

Results

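Kidney gene expression was compared between Dahl SS/Jr (S) rats, an inbred strain whose blood pressure rises on a salty diet, and 2 congenic strains, ET3x1 and ET3x2, which carry a chromosome segment of the salt-resistant R strain on the S background. All 26 rats were male. They ate a diet with 0.4% NaCl until 39 to 41 days of age, when part of each strain was moved to 4% NaCl for 24 hours. There were 5 S rats on low salt, 5 S rats on high salt and 4 rats in each of the other 4 groups. RNA of 1 kidney per rat was hybridised to 2 Affymetrix chips, RAE230A and RAE230B, giving 52 arrays. Array medians lay between 7.47 and 7.52 (log2) on RAE230A and between 6.34 and 6.40 on RAE230B. Changes are given as log2 differences ± the standard error of the limma fit, and adjusted p-values are limma's after Benjamini-Hochberg adjustment unless camera or Fisher's exact test is named.

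The comparison of ET3x2 with S bears on the stated interest of the series, genes with altered activity within the ET3x2 congenic region. Rtel1, a DNA helicase gene of distal chromosome 3, was 1.92-fold higher in the 8 ET3x2 than in the 10 S rats (0.94 ± 0.05, limma adjusted p = 1.2e-12). Of 17 tested markers of leukocytes 8 were higher, a list result by camera that was lost with an estimated correlation (adjusted p = 0.385). Among them were RT1-Db1 (0.48 ± 0.12), Coro1a (0.40 ± 0.09) and Fcer1g (0.39 ± 0.07), which encode a class II antigen-presenting chain, an actin-binding protein of leukocytes and an Fc receptor chain. Among podocyte genes of the glomerulus, the filtering unit, Podxl (-0.37 ± 0.06) and Synpo (-0.34 ± 0.06) were lower. The endothelial growth factor receptor gene Kdr was lower (-0.60 ± 0.07), and so was Slc12a1, the sodium, potassium and chloride cotransporter of the thick ascending limb (-0.51 ± 0.09).

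limma called 4415 of 15473 tested probe sets, 2254 higher and 2161 lower in ET3x2, with a median absolute change of 0.24 and 0 over 2-fold. After Rtel1, the highest were Mgll (0.85 ± 0.16), Tns1 (0.76 ± 0.10), Sf3b1 (0.73 ± 0.14), Alas2 (0.71 ± 0.27), Cd99 (0.70 ± 0.19) and Ap2s1 (0.68 ± 0.16), which encode monoacylglycerol lipase, the focal adhesion protein tensin, a splicing factor, the erythroid enzyme of heme synthesis, a cell surface glycoprotein and a clathrin adaptor subunit. They were followed by Ggt1 (0.67 ± 0.23), Get3 (0.65 ± 0.14), Bckdha (0.65 ± 0.15), Scand1 (0.65 ± 0.25) and Dapk3 (0.65 ± 0.18), of which Ggt1 encodes a brush border enzyme of glutathione breakdown and Bckdha a subunit of branched-chain amino acid breakdown. The lowest were the ubiquitin ligase gene Nedd4 (-0.77 ± 0.16), the semaphorin gene Sema3g (-0.75 ± 0.08) and Nrp1, for a semaphorin receptor (-0.65 ± 0.09), with Prrc2c (-0.73 ± 0.10), Ppp1cb (-0.72 ± 0.11), Cpe (-0.71 ± 0.09), Gatm (-0.71 ± 0.08) and Pls3 (-0.70 ± 0.09). Gatm makes the precursor of creatine, Cpe trims peptide hormones and Pls3 bundles actin. The list ended with Lrrc58 (-0.70 ± 0.10), Irs2 (-0.68 ± 0.14), Vcl (-0.65 ± 0.17) and Ddx3x (-0.65 ± 0.14), Irs2 being a substrate of the insulin receptor and Vcl the focal adhesion protein vinculin. For Tns1, Sf3b1 and Nedd4, 1 other probe set of the gene was called in the opposite direction, and the only other one of Bckdha, Sema3g and Nrp1 went the other way without a call. Of 263 genes with several called probe sets, 208 had all of them in the same direction. On low and on high salt apart, Tns1 differed by 1.33 ± 0.14 and 0.19 ± 0.14, Ggt1 by 0.21 ± 0.32 and 1.12 ± 0.32 and Vcl by -1.23 ± 0.24 and -0.08 ± 0.24, and 19 of the 24 genes differed more on low salt. With 1 rat left out at a time, Alas2 lost its call when any of 17 rats was left out (0.56 to 0.80 over all 26 rats), as did Scand1 for 21 (0.42 to 0.80) and Ggt1 for 6 (0.49 to 0.81).

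Of 17 tested leukocyte markers 8 rose and 0 fell, against 9 and 0 adjusted over the list alone (camera, adjusted p = 0.00810, and adjusted p = 0.385 with an estimated correlation). All 4 tested glomerulus markers fell, also when adjusted over the list alone (camera, adjusted p = 9.9e-04, and adjusted p = 0.355 with an estimated correlation). Of 19 genes of injury, matrix and fibrosis 9 fell and 1 rose, with the same counts adjusted over the list alone (camera, adjusted p = 9.9e-04, and adjusted p = 0.385 with an estimated correlation). The osteopontin gene Spp1 (-0.60 ± 0.09), the basement membrane collagen gene Col4a2 (-0.44 ± 0.08) and the adhesion molecule gene Vcam1 (-0.43 ± 0.08) fell most. Of 13 endothelium and smooth muscle markers 4 fell and 0 rose, as they did adjusted over the list alone, with Kdr (-0.60 ± 0.07) and Mylk (-0.42 ± 0.07) the furthest (camera, adjusted p = 0.00810, and adjusted p = 0.385 with an estimated correlation).

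Of 26 genes of tubular sodium, chloride and potassium transport 7 fell and 1 rose, with the same counts adjusted over the list alone. Slc12a1, the bicarbonate cotransporter gene Slc4a4 (-0.34 ± 0.07) and the kinase gene Wnk1 (-0.31 ± 0.06) fell most (camera, adjusted p = 0.00810, and adjusted p = 0.385 with an estimated correlation). Of 9 genes of the angiotensin and aldosterone system 3 fell and 0 rose, also adjusted over the list alone: the glucocorticoid receptor gene Nr3c1 (-0.38 ± 0.08) and the peptidase genes Enpep (-0.35 ± 0.06) and Mme (-0.28 ± 0.07), with camera at adjusted p = 0.0259, and adjusted p = 0.385 with an estimated correlation. Of 9 immediate early genes 3 fell, led by Egr1 (-0.53 ± 0.19) and Klf6 (-0.40 ± 0.08), as they did adjusted over the list alone (camera, adjusted p = 0.0451, and adjusted p = 0.495 with an estimated correlation), a call that ended with array medians centred (adjusted p = 0.0502). Egr1 differed by -0.01 ± 0.26 and -1.05 ± 0.26 on low and high salt. Sgk1, an aldosterone-induced kinase gene, differed by -0.05 ± 0.13 (limma adjusted p = 0.817), and Edn3 is not analysed here. Agt, for angiotensinogen, lay below the brightness filter, and without the filter it differed by 0.20 ± 0.09 (limma adjusted p = 0.0776).

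Called genes that were lower in ET3x2 had a median genomic span of 42.1 kb and those that were higher 12.7 kb, against 22.8 kb for all genes with a span. Spearman's correlation of log2 change with span was -0.30 across 8793 genes, which are not independent replicates. The log2 ratio of 3' to 5' Gapdh control signal, a sign of RNA integrity, was 0.948 ± 0.0665 (SD, n = 4) in ET3x2 and 0.827 ± 0.0723 (SD, n = 5) in S rats on low salt (exact permutation p = 0.0556, 0.145 after adjustment over 28 tests). With this ratio as a covariate 4055 of the 4415 probe sets were called again in the same direction. The median change of the 4415 was 0.985 of its size, and their median standard error went from 0.0650 to 0.0659. The bioD minus bioC spike-in difference, a sign of hybridisation, was 2.29 ± 0.143 (SD, n = 4) in ET3x2 and 2.83 ± 0.113 (SD, n = 5) in S rats on low salt (RAE230A, exact permutation p = 0.00794, 0.111 after adjustment). On high salt it was 2.67 and 2.37 (exact permutation p = 0.437). With this difference as a covariate calls on low salt went from 2817 to 1437.

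**Figure D1:**
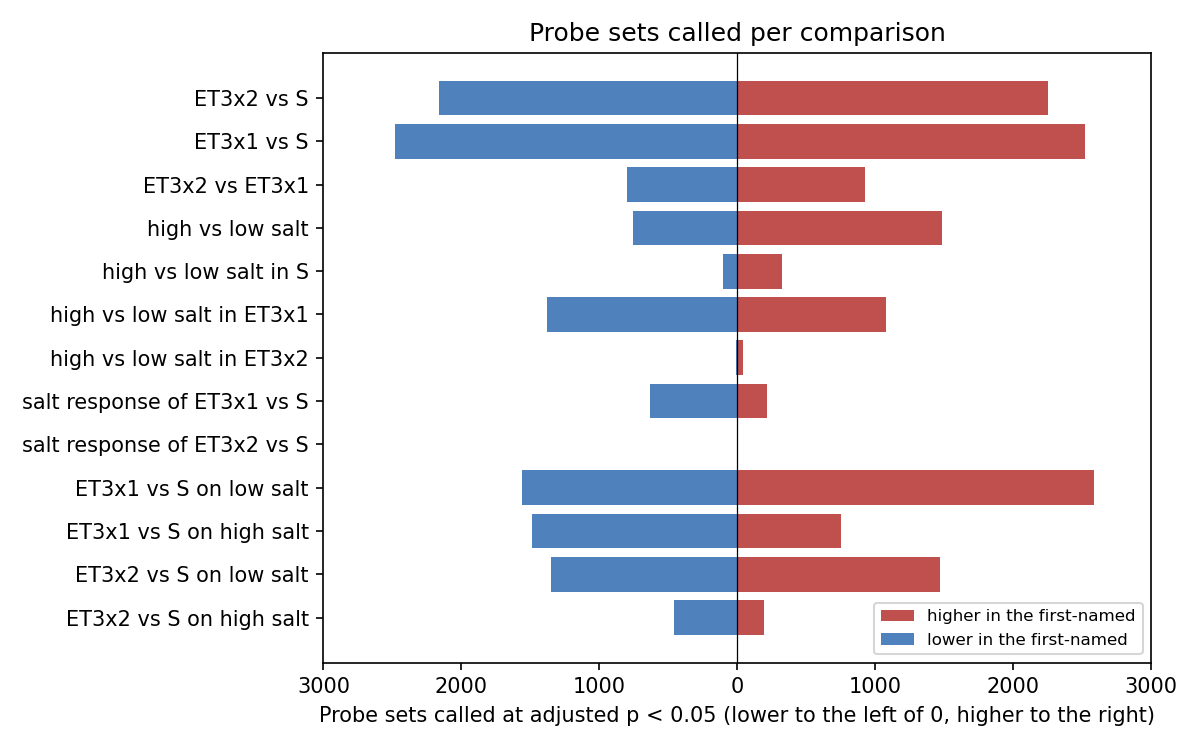
Number of probe sets called at adjusted p below 0.05 in each of 13 comparisons, lower to the left of 0 and higher to the right, over 15473 tested probe sets. The comparison of ET3x1 with S has the most calls, 5001, and the difference between the salt responses of ET3x2 and S has 3.

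Whether calls gathered near the congenic segment was asked next. Along chromosome 3, in the gene order of the GRCr8 table, Rtel1 was number 659 of 669 tested genes, 11 from the end. Both of its probe sets were higher, by 0.94 ± 0.05 and 0.32 ± 0.06 in ET3x2 and by 0.71 ± 0.05 and 0.22 ± 0.06 in ET3x1. Of the 57 tested genes on the distal chromosome 3 list, 14 rose and 3 fell in ET3x2, with the same counts adjusted over the list alone, and 12 rose and 8 fell in ET3x1, against 12 and 9 adjusted over the list alone. In ET3x2 the furthest were Pcmtd2 (0.45 ± 0.11), Rbm38 (0.42 ± 0.12), Ctsz (0.41 ± 0.08) and Atp9a (0.34 ± 0.09), Ctsz being the lysosomal protease cathepsin Z and Atp9a a lipid flippase gene. In ET3x1 they were Ube2v1 (0.49 ± 0.15), Ppp1r3d (0.46 ± 0.07) and Zfp217 (-0.37 ± 0.06).

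The share of called genes on the list was compared with the share elsewhere. In ET3x2 17 of the 57 were called, 29.8% against 30.9% (Fisher's exact test, odds ratio 0.952, 95% interval 0.505 to 1.72, p = 1). In ET3x1 20 were called, 35.1% against 32.1% (Fisher's exact test, odds ratio 1.14, 95% interval 0.626 to 2.02, p = 0.67). The list as a whole had adjusted p = 0.213 in ET3x2 by camera, and adjusted p = 0.679 with an estimated correlation. Of all 669 tested genes of chromosome 3, 209 were called in ET3x2 (31.2%, against 30.8% elsewhere, Fisher's exact test, adjusted p = 0.915), and 0 of 21 chromosomes stood apart. The ends of the congenic segments are not given in the labels, so the list stands for the neighbourhood of Edn3 and not for a segment.

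**Figure D2:**
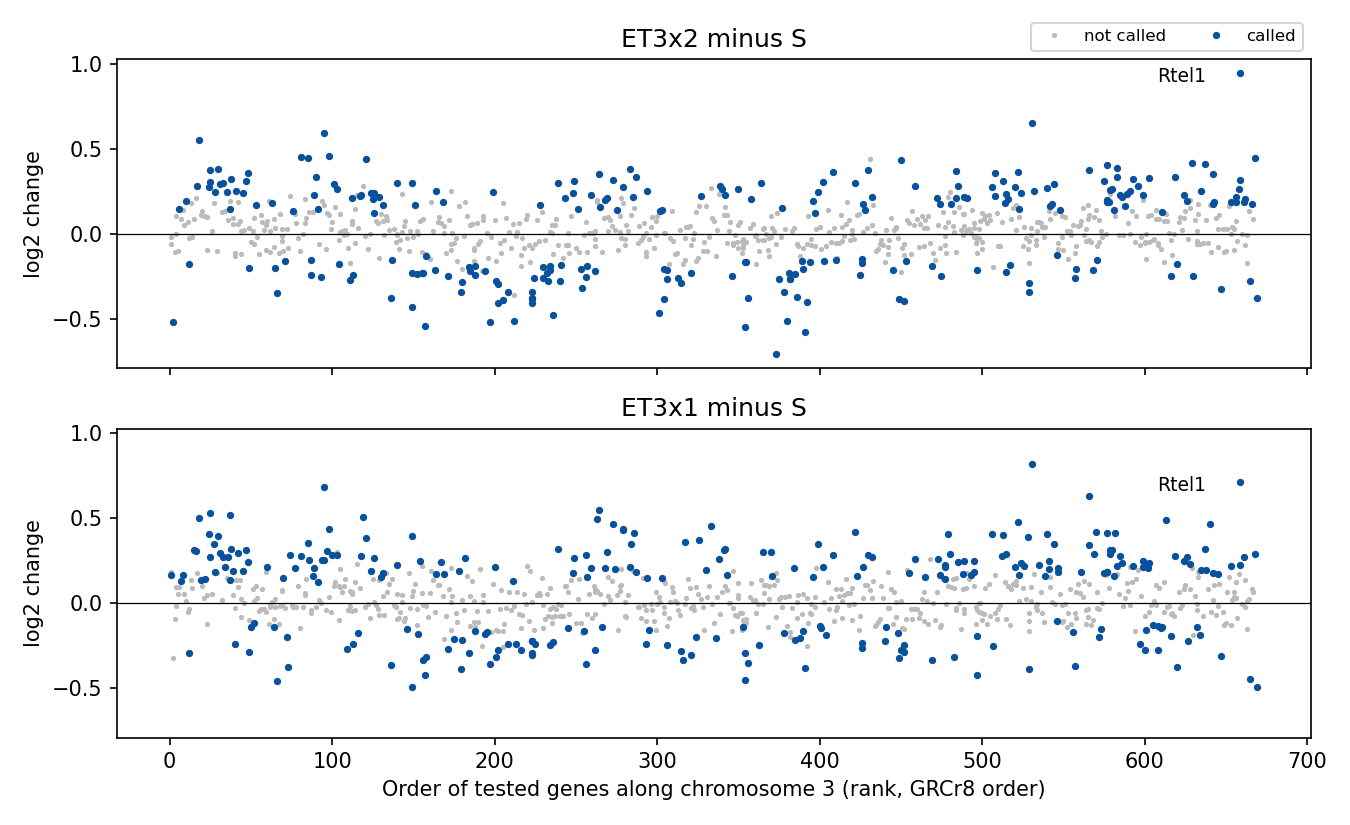
Log2 change of each tested probe set on chromosome 3 for ET3x2 minus S (top) and ET3x1 minus S (bottom), by gene order, with probe sets called at adjusted p below 0.05 in colour. Rtel1 lies at 0.94 in ET3x2 and 0.71 in ET3x1, and called probe sets occur along the whole chromosome.

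ET3x1 was the other congenic strain set against S. Ap2s1 was 2.03-fold higher in the 8 ET3x1 than in the 10 S rats (1.02 ± 0.16, limma adjusted p = 9.5e-05), and Cd99 was 1.98-fold higher (0.99 ± 0.19). Of 12 tested genes of the circadian clock 6 were lower, a list result by camera that was lost with an estimated correlation (adjusted p = 0.0761). Among them were Per3 (-0.65 ± 0.07), Bhlhe40 (-0.61 ± 0.16) and Nr1d2 (-0.52 ± 0.09), all repressors within the clock. The podocyte genes Podxl (-0.53 ± 0.06) and Synpo (-0.50 ± 0.06) were lower, as was the endothelial Kdr (-0.58 ± 0.07).

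limma called 5001 probe sets, 2523 higher and 2478 lower, with a median absolute change of 0.24 and 2 over 2-fold. These were Ap2s1 and a probe set without a single gene symbol (-1.48 ± 0.15, limma adjusted p = 3.3e-07). The ranking of named genes leaves out probe sets of the latter kind. Other genes at the top were Metrn (0.82 ± 0.12), Scand1 (0.82 ± 0.25), Ggt1 (0.73 ± 0.23), Get3 (0.72 ± 0.14), Cdkn2c (0.72 ± 0.09) and Mettl26 (0.71 ± 0.13), Cdkn2c encoding an inhibitor of cyclin-dependent kinases. At the bottom were Cpe (-0.81 ± 0.09), Anp32a (-0.80 ± 0.30), Tsc22d2 (-0.79 ± 0.17) and Il6st (-0.79 ± 0.09), the last a receptor subunit of the interleukin-6 family, and Fat1 (-0.75 ± 0.07), Egr1 (-0.75 ± 0.19), Gnb1 (-0.71 ± 0.16) and Atp8b1 (-0.67 ± 0.09), which encode a large cadherin, an immediate early transcription factor, a G protein subunit and a lipid flippase. For Gnb1 both other probe sets were called in the opposite direction, and for Atp8b1 the only other one went the other way without a call. Anp32a lost its call when any of 13 rats was left out (-0.99 to -0.68 over all 26 rats). Sgk1 differed by -0.27 ± 0.13 (limma adjusted p = 0.109) and was called when either of 2 rats was left out. Without the filter Agt differed by 0.0849 ± 0.0852 (limma adjusted p = 0.470). On low and on high salt apart, Gnb1 differed by -1.37 ± 0.23 and -0.05 ± 0.23 and Scand1 by 1.41 ± 0.35 and 0.22 ± 0.35. The widely spread S rats on high salt (SD 1.19 for Ggt1) also enter the change of Ggt1 in ET3x1.

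Of 12 clock genes 6 fell and 0 rose, against 7 and 0 adjusted over the list alone (camera, adjusted p = 9.1e-04, and adjusted p = 0.0761 with an estimated correlation). Of 4 glomerulus markers 3 fell, also adjusted over the list alone (camera, adjusted p = 9.1e-04, and adjusted p = 0.172 with an estimated correlation). Of 19 injury, matrix and fibrosis genes 5 fell and 1 rose, with the same counts adjusted over the list alone, led by Spp1 (-0.64 ± 0.09) and the connective tissue growth factor gene Ccn2 (-0.37 ± 0.11), with camera at adjusted p = 0.0230, and adjusted p = 0.846 with an estimated correlation. Of 9 immediate early genes 3 fell, also adjusted over the list alone, led by Egr1 (-0.75 ± 0.19) and Klf6 (-0.32 ± 0.08) (camera, adjusted p = 0.0380, and adjusted p = 0.846 with an estimated correlation). That call ended with the mean of a gene's probe sets (adjusted p = 0.0525) and with quantile normalization (adjusted p = 0.0576). Leukocyte markers gave 7 higher and 1 lower of 17 (camera, adjusted p = 0.127). Median span was 49.2 kb for called genes that were lower and 11.7 kb for those that were higher, with Spearman's correlation at -0.34, again across genes that are not independent replicates. On high salt the log2 ratio of 3' to 5' Gapdh signal on RAE230A was 0.594 ± 0.0265 (SD, n = 4) in ET3x1 and 0.812 ± 0.0526 (SD, n = 5) in S rats (exact permutation p = 0.00794, 0.111 after adjustment over 28 tests). On low salt it was 0.877 and 0.827 (exact permutation p = 0.405). The beta-actin ratio was 0.609 and 0.923 on high salt (exact permutation p = 0.0397, 0.145 after adjustment). With the Gapdh ratio as a covariate 3696 of the 5001 probe sets were called again in the same direction. The median change of the 5001 was 0.990 of its size, and their median standard error went from 0.0644 to 0.0721.

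Whether both strains differed from S in the same way was asked of all tested probe sets. Of these, 1196 were higher in both strains, 1133 lower in both and 11 called in opposite directions, whereas independent lists of these sizes would share 368 higher and 346 lower. Because both strains were set against the same S rats, data without differences were also simulated. In 100 simulations the covariance of the changes averaged 0.00232 and reached 0.00596, against 0.0219 observed, and their correlation averaged 0.423 and reached 0.747, so that the 0.696 observed lay within the range of the simulations. With separate S rats for each strain, the median over 100 splits was 314.5 shared higher (218 to 678) and 428.5 shared lower (363 to 569), with 7 in opposite directions (0 to 188). The median covariance was 0.0199 and the median correlation 0.587. The numbers that independent lists would share were not computed for these smaller fits, so the shared counts cannot be set against the 368 and 346.

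Set against each other, ET3x2 rats had lower levels than ET3x1 rats of Gba3, a cytosolic beta-glucosidase gene (-1.03 ± 0.24), of the mitochondrial COX1 (-0.93 ± 0.18), of Gatm (-0.88 ± 0.09, limma adjusted p = 2.3e-06) and of the transcription factor gene Maf (-0.61 ± 0.11), with 8 rats per strain. Tns1 (0.72 ± 0.11), Cpd (0.55 ± 0.14), Ccar1 (0.54 ± 0.15) and Atxn2 (0.54 ± 0.09) were highest in ET3x2. These values average the diets. On low and on high salt apart they were -0.26 ± 0.35 and -1.80 ± 0.35 for Gba3, 0.18 ± 0.15 and 1.25 ± 0.15 for Tns1, 0.13 ± 0.20 and 0.97 ± 0.20 for Cpd, 0.25 ± 0.21 and 0.84 ± 0.21 for Ccar1 and 0.28 ± 0.13 and 0.79 ± 0.13 for Atxn2, larger with the ET3x1 rats on high salt, the group with the lowest mean 3' to 5' Gapdh ratio, and -1.42 ± 0.26 and -0.44 ± 0.26 for COX1, -0.91 ± 0.16 and -0.31 ± 0.16 for Maf and -1.02 ± 0.13 and -0.75 ± 0.13 for Gatm, larger on low salt. The change of these differences with diet was not tested. Without the filter Sgk1 differed by 0.22 ± 0.13 and Agt by 0.12 ± 0.09 (limma adjusted p = 0.287 and 0.404). Of 12 clock genes 2 rose and 0 fell, Per1 (0.42 ± 0.11) and Per3 (0.36 ± 0.07), against 5 and 0 adjusted over the list alone (camera, adjusted p = 0.0150, and adjusted p = 0.326 with an estimated correlation). Of 21 genes of oxidative stress defence 1 rose and 3 fell, against 1 and 5 adjusted over the list alone, with the glutathione synthesis gene Gclm (-0.51 ± 0.09) and catalase, Cat (-0.50 ± 0.09), the furthest (camera, adjusted p = 0.0150, and adjusted p = 0.326 with an estimated correlation). That list's camera call ended with quantile normalization (adjusted p = 0.190). limma called 1725 probe sets, 929 higher and 796 lower in ET3x2. The count was 842 without ET3x1 low-salt rat 1 and 1047 without ET3x1 high-salt rat 3, and the higher calls made up 53.9%, or 37.7% with array medians centred. With the Gapdh covariate 462 were called. For Tns1, 1 of 3 other probe sets was called in the opposite direction, and the only other one of Gatm went the other way without a call.

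The other factor was diet. After 24 hours on 4% NaCl, 13 of 18 tested cholesterol synthesis genes were higher and 1 lower over the 3 strains. Among the higher were Idi1 (0.81 ± 0.09), Sqle (0.67 ± 0.06), Cyp51 (0.51 ± 0.10) and Msmo1 (0.47 ± 0.07), Sqle at a limma adjusted p = 7.8e-08. Of 19 tested genes of cell division 11 were higher, among them Pcna (0.50 ± 0.06), Top2a (0.34 ± 0.07) and Rrm1 (0.34 ± 0.07). By camera both lists were called, and both calls were lost with an estimated correlation (adjusted p = 0.147 and 0.156). The cell division genes named encode the sliding clamp of replication, topoisomerase II and a ribonucleotide reductase subunit. Spp1, for osteopontin, was higher by 0.65 ± 0.07. Casr, the calcium-sensing receptor gene, was lower (-0.51 ± 0.07; -0.52 ± 0.11 in S, -0.64 ± 0.12 in ET3x1 and -0.36 ± 0.12 in ET3x2). Slc5a3, the myo-inositol transporter gene, was lower on average (-0.56 ± 0.12), with -0.16 ± 0.19 in S, -1.33 ± 0.21 in ET3x1 and -0.20 ± 0.21 in ET3x2, and its response differed between ET3x1 and S (limma adjusted p = 0.0175). These values compare 13 rats on high salt with 13 on low salt, averaged over strains unless a strain is named.

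Signs of RNA integrity were compared between diets. On RAE230A the log2 ratio of 3' to 5' Gapdh signal was 0.594 ± 0.0265 (SD, n = 4) in ET3x1 rats on high salt and 0.877 ± 0.0994 (SD, n = 4) on low salt (exact permutation p = 0.0286, the smallest 4 against 4 can give, and 0.145 after adjustment over 28 tests). It was 0.747 ± 0.107 and 0.948 ± 0.0665 (SD, n = 4) in ET3x2 rats, and 0.812 ± 0.0526 and 0.827 ± 0.0723 (SD, n = 5) in S rats. The bioD minus bioC spike-in difference, a sign of hybridisation, was 3.08 ± 0.150 in ET3x1 rats on high and 2.54 ± 0.236 on low salt (SD, n = 4) on RAE230A (exact permutation p = 0.0286, 0.145 after adjustment), and 3.03 ± 0.125 and 2.23 ± 0.168 on RAE230B, where it was not tested. With the Gapdh ratio as a covariate 25 probe sets were called for salt in place of 2239. The median change of the 2239 was then 0.785 of its size without the covariate, and their median standard error went from 0.0552 to 0.0871. Called genes of the cholesterol, cell division and injury lists went from 14 to 2, 11 to 1 and 10 to 0 with the covariate, the last with 7 at an unadjusted p under 0.05, as their median standard errors rose from 0.0590 to 0.0940, 0.0625 to 0.0976 and 0.0614 to 0.0999 and their median changes went from 0.24 to 0.26, 0.22 to 0.27 and 0.19 to 0.14. For camera the RAE230A ratio of each rat was the covariate for genes of both chips, whereas limma used each chip's own ratio. By camera with that covariate, at the preset correlation, the cholesterol, cell division and injury lists had adjusted p = 5.7e-13, 2.8e-14 and 5.2e-07, and heat shock (lower) and interferon (higher) genes, not called without it (adjusted p = 0.120 and 0.0627), had adjusted p = 0.00662 and 0.00895. With an estimated correlation and the covariate the 5 lists had adjusted p = 0.0483, 0.0483, 0.139, 0.385 and 0.385, so that the calls of cholesterol and cell division genes held by a narrow margin and the other 3 were lost. Sqle was 0.63 ± 0.10 (limma adjusted p = 0.00501), Pcna 0.47 ± 0.09 (limma adjusted p = 0.0282) and Spp1 0.49 ± 0.11 (limma adjusted p = 0.0680) with the covariate.

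**Figure D3:**
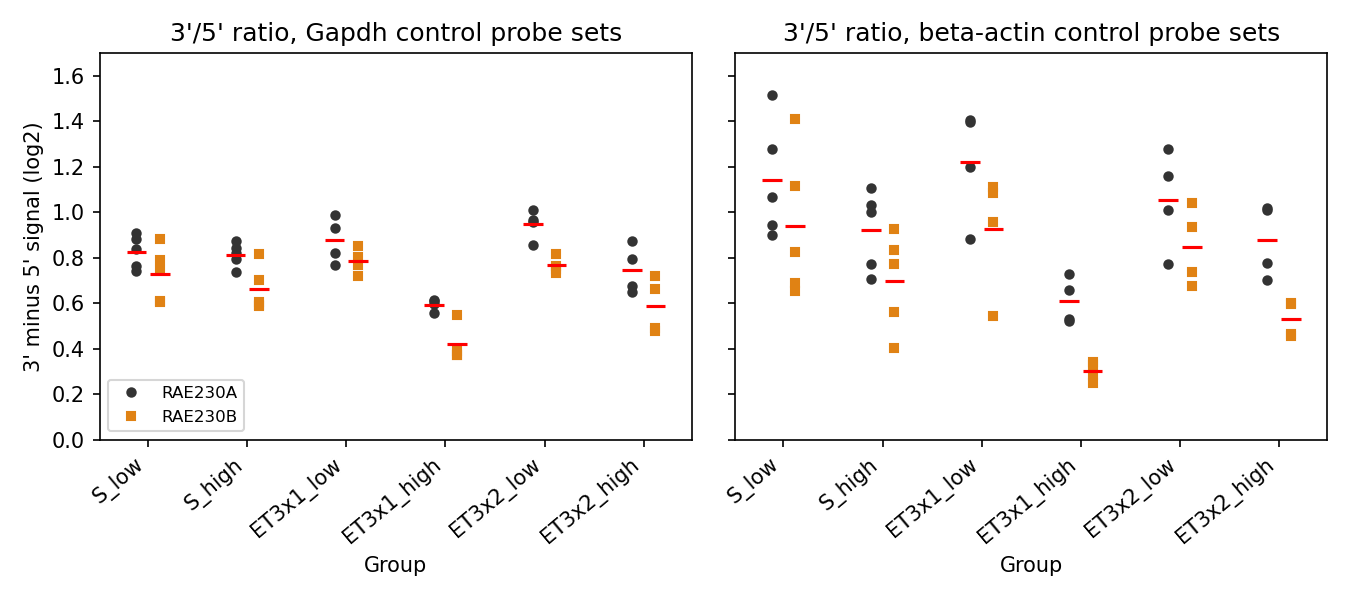
Log2 ratio of 3' to 5' signal of the Gapdh (left) and beta-actin (right) control probe sets for each rat, circles RAE230A and squares RAE230B, with red lines at the group means. ET3x1 rats on high salt have the lowest mean for both genes on both chips, 0.594 for Gapdh and 0.609 for beta-actin on RAE230A.

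For salt limma called 2239 probe sets, 1487 higher and 752 lower, and the higher calls made up 66.4%, or 55.5% with quantile normalization. With array weights 4234 were called. The highest genes were the fatty acid desaturase gene Scd2 (0.91 ± 0.15), the stress-responsive Ndrg1 (0.89 ± 0.10) and Mat2a, which makes S-adenosylmethionine (0.87 ± 0.13), followed by Plekhb2 (0.85 ± 0.15), Mmut (0.82 ± 0.11), App (0.81 ± 0.14) and Acmsd (0.76 ± 0.09). Mmut and Acmsd are enzymes of propionate and tryptophan breakdown. Actr3 (0.75 ± 0.10), Eif4g2 (0.75 ± 0.13), Cxcl12 (0.75 ± 0.14), Tpm4 (0.74 ± 0.08) and St6gal1 (0.74 ± 0.14) completed the top, with Actr3 and Tpm4 belonging to the actin skeleton and Cxcl12 encoding a chemokine. The lowest besides Slc5a3 and Casr were Srrm2 (-0.56 ± 0.15), Gosr1 (-0.53 ± 0.14), Psma7 (-0.48 ± 0.08), Etv1 (-0.48 ± 0.08) and Prom1 (-0.48 ± 0.08), for a splicing protein, a Golgi vesicle protein, a proteasome subunit, a transcription factor and prominin. Usp33 (-0.47 ± 0.10), Anks1a (-0.46 ± 0.10), Foxq1 (-0.46 ± 0.11), Itgb6 (-0.44 ± 0.10) and COX1 (-0.44 ± 0.14) came next, Itgb6 being an epithelial integrin. The only other probe set of Gosr1, Psma7 and Usp33 went the other way without a call. Of these 24 genes 21 changed most in ET3x1. Srrm2 changed by -0.12 ± 0.24 in S, -1.67 ± 0.27 in ET3x1 and 0.10 ± 0.27 in ET3x2 (difference in response of ET3x1 from S, limma adjusted p = 0.0150), and in the same order St6gal1 by 0.22 ± 0.23, 1.46 ± 0.25 and 0.54 ± 0.25 (adjusted p = 0.0334 for that difference), Gosr1 by -0.65 ± 0.23, -0.79 ± 0.26 and -0.16 ± 0.26, Foxq1 by -0.10 ± 0.18, -0.64 ± 0.20 and -0.63 ± 0.20 and COX1 by -0.63 ± 0.23, -0.83 ± 0.26 and 0.14 ± 0.26 (0.852, 0.231 and 0.764). COX1 lost its call when any of 14 rats was left out (-0.55 to -0.37 over all 26 rats). Sgk1 differed by -0.27 ± 0.11 (limma adjusted p = 0.0857) and was called when any of 3 rats was left out. Without the filter the change of Agt was -0.31 ± 0.07 (limma adjusted p = 0.00521).

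Of 18 cholesterol synthesis genes 13 rose and 1 fell, against 14 and 1 adjusted over the list alone (camera, adjusted p = 1.9e-10, and adjusted p = 0.147 with an estimated correlation). Mvd, for mevalonate diphosphate decarboxylase, fell (-0.21 ± 0.06). Of 19 cell division genes 11 rose and 0 fell, against 12 and 0 adjusted over the list alone (camera, adjusted p = 6.2e-09, and adjusted p = 0.156 with an estimated correlation). Of 19 genes of injury, matrix and fibrosis 10 rose and 0 fell, against 13 and 0 adjusted over the list alone, with Spp1 (0.65 ± 0.07) and Vim (0.30 ± 0.07) the furthest (camera, adjusted p = 3.0e-08, and adjusted p = 0.156 with an estimated correlation). Of 17 leukocyte markers 2 rose, Coro1a (0.25 ± 0.07) and Csf1r (0.15 ± 0.05), also adjusted over the list alone (camera, adjusted p = 0.0301, and adjusted p = 0.521 with an estimated correlation). In S, ET3x1 and ET3x2 apart Coro1a changed by 0.53 ± 0.12, -0.01 ± 0.13 and 0.23 ± 0.13, Csf1r by 0.17 ± 0.07, 0.02 ± 0.08 and 0.26 ± 0.08, Mvd by -0.06 ± 0.09, -0.33 ± 0.11 and -0.23 ± 0.11 and Podxl by -0.04 ± 0.08, -0.24 ± 0.08 and -0.21 ± 0.08. Of 12 clock genes 1 fell, Per3 (-0.28 ± 0.06), against 5 adjusted over the list alone (camera, adjusted p = 0.0311, and adjusted p = 0.205 with an estimated correlation). The smooth muscle genes Tagln (0.52 ± 0.10) and Acta2 (0.42 ± 0.06) rose, the podocyte genes Synpo (-0.17 ± 0.05) and Podxl (-0.16 ± 0.05) fell, and the potassium channel gene Kcnj1 (0.69 ± 0.13) and Slc4a4 (0.38 ± 0.06) rose. With the Gapdh covariate limma called 0 genes of the leukocyte, clock, glomerulus and tubular transport lists, with 0, 2, 1 and 4 at an unadjusted p under 0.05, as the median standard error of each list rose from 0.0590 to 0.0951, 0.0701 to 0.115, 0.0555 to 0.0905 and 0.0533 to 0.0852. The median change went from 0.0844 to 0.0494, -0.121 to -0.114, -0.0886 to -0.0877 and -0.00254 to -0.0244, and camera gave adjusted p = 0.0558, 0.00477, 0.0724 and 0.245 with the RAE230A ratio as the covariate for both chips at the preset correlation, and adjusted p = 0.526, 0.102, 0.385 and 0.695 with an estimated one.

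The salt response was then taken within each strain. In ET3x1 rats Nedd4 was 3.36-fold higher on high salt (1.75 ± 0.24, 4 rats against 4, limma adjusted p = 3.5e-05), followed by Mmut (1.64 ± 0.19), Plekhb2 (1.59 ± 0.26) and Actr3 (1.55 ± 0.17). Evi5 (-1.75 ± 0.23), Srrm2 (-1.67 ± 0.27), Ccdc6 (-1.39 ± 0.20) and Slc5a3 (-1.33 ± 0.21) were lowest. In S rats Evi5 (1.30 ± 0.20), Pbrm1 (1.04 ± 0.20), Crim1 (1.00 ± 0.15) and Scd2 (0.97 ± 0.25) were highest, Pbrm1 being a chromatin remodelling subunit, and Kpna1 (-1.06 ± 0.25), Ythdf2 (-0.93 ± 0.20), Vcl (-0.81 ± 0.22) and Bhlhe40 (-0.81 ± 0.21) lowest, with Kpna1 a nuclear import receptor and Ythdf2 a reader of methylated RNA. In ET3x2 rats Ndrg1 (0.92 ± 0.17), Idi1 (0.77 ± 0.16), Ppp1cb (0.73 ± 0.16) and Apcs (0.73 ± 0.11) were highest and Noct (-0.49 ± 0.10), Tob2 (-0.44 ± 0.09), Sik1 (-0.40 ± 0.07) and Zfp703 (-0.38 ± 0.07) lowest, Noct being a rhythmically expressed gene and Sik1 that of a salt-inducible kinase. For Nedd4 in ET3x1, 1 of 4 other probe sets was called in the opposite direction. The only other probe set of Evi5 and that of Plekhb2 went the other way in ET3x1 without a call. With 1 rat left out, calls were lost in S for Bhlhe40 (4), Kpna1 (2), Scd2 (5) and Vcl (16) and in ET3x2 for Idi1 (5), Ndrg1 (3), Noct (6), Ppp1cb (15), Sik1 (2), Tob2 (5) and Zfp703 (3), the number of rats whose absence did so in brackets. Without the filter, in S, ET3x1 and ET3x2, Sgk1 changed by -0.32 ± 0.17, -0.31 ± 0.19 and -0.19 ± 0.19 (limma adjusted p = 0.384, 0.330 and 0.781) and Agt by -0.24 ± 0.11, -0.33 ± 0.13 and -0.36 ± 0.13 (limma adjusted p = 0.329, 0.100 and 0.235). For Scd2 in S, high-salt rats 1 and 2 had 10.15 and 9.77 and the other 3 rats 8.73 to 8.92, and their bioD minus bioC spike-in difference on RAE230A was 1.65 and 1.55, against 2.83 to 2.94. Without these 2 rats the change of Scd2 in S was 0.52 (limma adjusted p = 0.364), and Pbrm1, Kpna1, Ythdf2, Vcl and Bhlhe40 lost their calls too (0.92, -0.91, -0.89, -0.76 and -0.71).

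In ET3x1, 2457 probe sets were called between high and low salt, 1080 higher and 1377 lower on high salt. This count was 1354 without ET3x1 low-salt rat 2, 1353 without ET3x1 low-salt rat 3 and 1511 without ET3x1 high-salt rat 3. With the Gapdh ratio as a covariate it was 6, and the median change of the called probe sets 0.836 of its size as their median standard error went from 0.101 to 0.158. With the spike-in difference as a covariate 897 of the 2457 were called again, the median change being 0.935 of its size and the median standard error 0.126. In S rats 430 were called, 327 higher and 103 lower, 376 with the covariate. The count in S was 174 without S low-salt rat 1, 235 without S low-salt rat 2, 871 without S low-salt rat 3, 145 without S low-salt rat 4, 1000 without S low-salt rat 5, 195 without S high-salt rat 1, 156 without S high-salt rat 2 and 268 without S high-salt rat 4. In ET3x2 rats 47 were called, 40 higher and 7 lower, and 0 with the covariate. That count was 73 without S low-salt rat 1, 17 without ET3x2 low-salt rat 2, 149 without ET3x2 low-salt rat 3, 14 without ET3x2 low-salt rat 4, 1 without ET3x2 high-salt rats 1 or 3, 26 without ET3x2 high-salt rat 2 and 294 without ET3x2 high-salt rat 4. With quantile normalization the higher calls made up 57.7% in place of 76.0% in S and 73.5% in place of 85.1% in ET3x2. In a fit of the strain alone 77 were called in S and 1 in ET3x2. With array weights the counts were 1091 in S, 4803 in ET3x1 and 1140 in ET3x2.

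Whether strains responded differently to salt was tested itself. The response of 850 probe sets differed between ET3x1 and S, 219 higher and 631 lower in ET3x1, led by Evi5 (-3.05 ± 0.30), Tns1 (-2.21 ± 0.20), Ccdc6 (-1.91 ± 0.27) and Cpd (-1.82 ± 0.27) on the lower side and Vcl (1.83 ± 0.34), Kpna1 (1.60 ± 0.37), Peli2 (1.58 ± 0.27) and Sppl2a (1.47 ± 0.22) on the higher. Without a call, the only other Evi5 probe set and both others of Kpna1 went the other way in this comparison. With quantile normalization 43.8% were higher in place of 25.8%. With the Gapdh covariate 27 were called, the median change of the 850 being 0.894 of its size and their median standard error 0.180 in place of 0.139. With the spike-in covariate 56 of the 850 were called again, the median change being 0.894 of its size and the median standard error 0.173. The count was 566 without S low-salt rat 1, 549 without S high-salt rat 2, 1547 without ET3x1 low-salt rat 1, 313 without ET3x1 low-salt rat 2, 308 without ET3x1 low-salt rat 3, 434 without ET3x1 high-salt rat 3 and 479 without ET3x1 high-salt rat 4, and 2388 with array weights. Between ET3x2 and S the response differed for 3 by limma, with 1390 at an unadjusted p under 0.05: the skeletal muscle myosin gene Myh1 (0.74 ± 0.13), Tns1 (-1.14 ± 0.20) and the growth factor receptor gene Igf1r (-0.77 ± 0.14), at limma adjusted p = 0.0493, 0.0493 and 0.0497. The count was 0 without S low-salt rats 1, 2 or 4, S high-salt rats 2, 3, 4 or 5, ET3x1 high-salt rat 3, ET3x2 low-salt rats 1, 2 or 4 or ET3x2 high-salt rats 1, 2 or 3, 20 without S low-salt rat 3, 43 without ET3x2 low-salt rat 3 and 44 without ET3x2 high-salt rat 4, and 416 with array weights.

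Strain differences were also taken on each diet. ET3x1 and S differed in 4150 probe sets on low salt, 2587 higher and 1563 lower, and the count was 2448 without ET3x1 low-salt rat 2. On high salt they differed in 2246, 756 and 1490, and the count was 1202 without ET3x1 high-salt rat 3 and 1126 without ET3x1 high-salt rat 4. With quantile normalization the higher calls made up 51.9% in place of 62.3% on low and 44.7% in place of 33.7% on high salt. ET3x2 and S differed in 2817 on low salt, 1469 and 1348, and the count was 1345 without ET3x2 low-salt rat 1 and 1773 without ET3x2 low-salt rat 2. On high salt they differed in 658, 198 and 460, and the count was 216 without S high-salt rat 1, 235 without S high-salt rat 2, 293 without S high-salt rat 3, 79 without ET3x2 high-salt rat 2 and 112 without ET3x2 high-salt rat 4. With the Gapdh covariate the count for ET3x1 on high salt was 227 and that for ET3x2 on low salt 1542. With array weights that for ET3x2 on high salt was 1319. Rtel1 values of S rats lay apart from those of both congenic strains on either diet. The mean log2 value was 7.18 ± 0.06 on low and 7.15 ± 0.07 on high salt in S rats (SD, n = 5), 7.99 ± 0.04 and 7.75 ± 0.15 in ET3x1 (SD, n = 4), and 8.20 ± 0.18 and 8.02 ± 0.06 in ET3x2 (SD, n = 4).

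**Figure D4:**
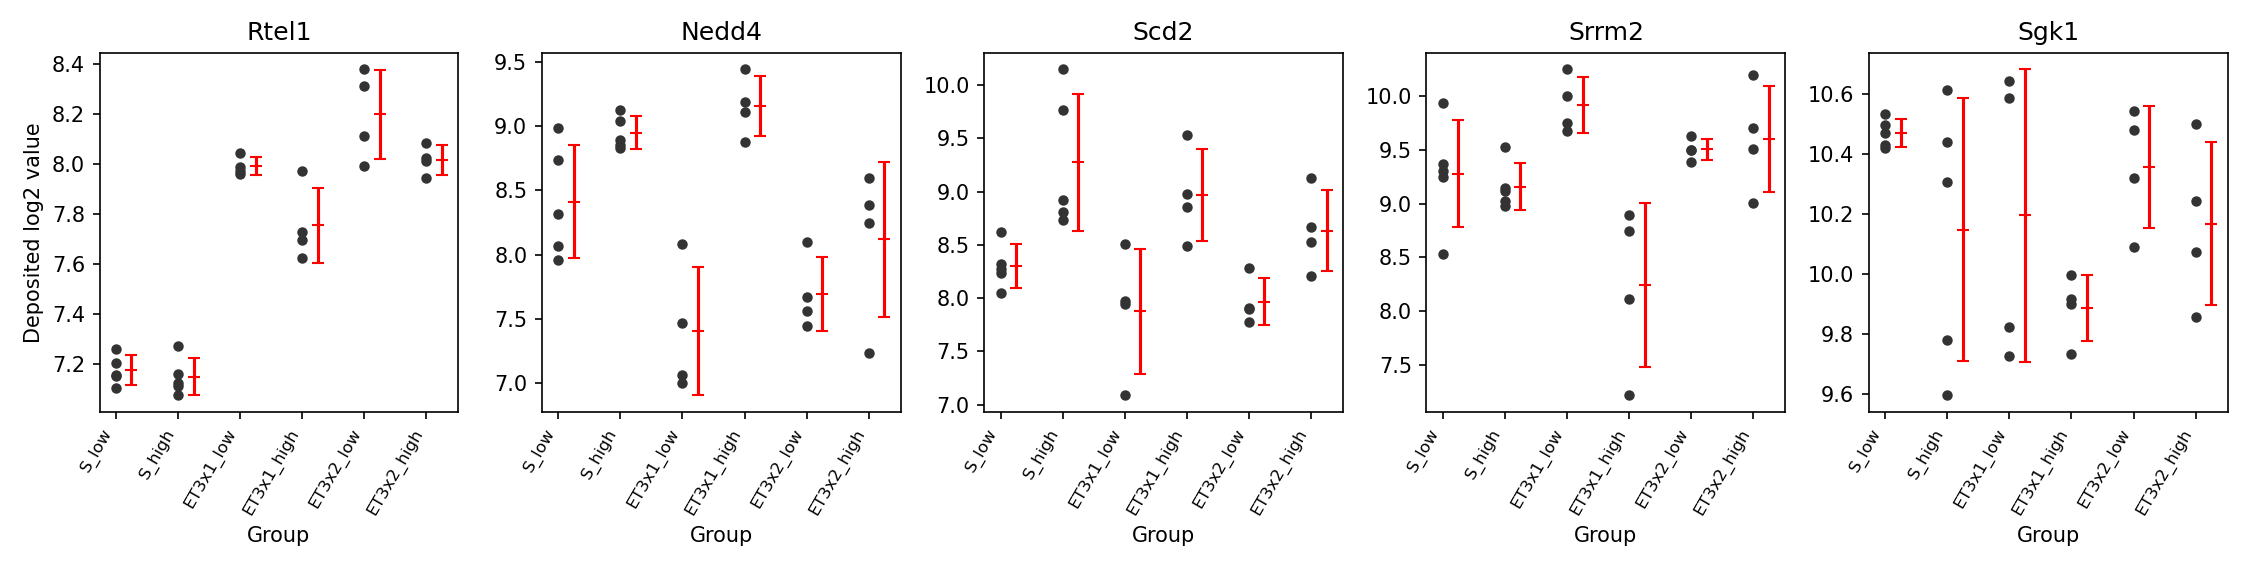
Deposited log2 values of single rats (black) with group mean and SD (red) for Rtel1, Nedd4, Scd2, Srrm2 and Sgk1 in the 6 groups. Every S rat lies below every congenic rat for Rtel1, with group means of 7.18 and 7.15 in S and 7.75 or more in the congenic strains.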

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

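The gene span test, the 6 Rtel1 tests, the tests on the median change of the difference in salt response, the 2 spike-in tests and the beta-actin covariate among the alternatives were chosen only after the result was seen, and the requirement that a ratio pass its bound by over 2 jackknife standard errors was added after the ratios were seen. In ET3x1 rat 3 on high salt the 3' to 5' Gapdh ratio on RAE230B was 0.548, with the other 3 rats of its group between 0.373 and 0.392. In ET3x1 rat 2 on low salt the bioD minus bioC difference on RAE230B was 1.98, with the other 3 between 2.29 and 2.34. Of 66 groups of values tested 2 held such a sample, and chance gives about 1 in 20. The salt response differed from that of S in 850 probe sets for ET3x1 and in 3 for ET3x2, by the test of the difference itself. The first count was 566 without S low-salt rat 1, 549 without S high-salt rat 2, 1547 without ET3x1 low-salt rat 1, 313 without ET3x1 low-salt rat 2, 308 without ET3x1 low-salt rat 3, 434 without ET3x1 high-salt rat 3 and 479 without ET3x1 high-salt rat 4, and 2388 with array weights. The second was 0 without S low-salt rats 1, 2 or 4, S high-salt rats 2, 3, 4 or 5, ET3x1 high-salt rat 3, ET3x2 low-salt rats 1, 2 or 4 or ET3x2 high-salt rats 1, 2 or 3, 20 without S low-salt rat 3, 43 without ET3x2 low-salt rat 3 and 44 without ET3x2 high-salt rat 4, and 416 with array weights.

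ET3x2 differed from S in 4415 and ET3x1 in 5001 probe sets, by a median of 0.24 in either. For the differences averaged over diets, RNA integrity as the Gapdh ratio shows it is argued against as the whole cause. With that ratio as a covariate the median change of the called probe sets was 0.986 of its size (jackknife SE 0.0228). Then 4055 of 4415 and 3696 of 5001 were called again in the same direction, as the median standard error went from 0.0650 to 0.0659 and from 0.0644 to 0.0721. These averages left the covariate little to remove, since the ratio differed from S in opposite directions on low and high salt (0.121 and -0.0651 in ET3x2, 0.0495 and -0.219 in ET3x1, RAE230A). On single diets RNA integrity stays open: calls went from 2246 to 227 for ET3x1 on high salt and from 2817 to 1542 for ET3x2 on low salt. The counts for the other diet stayed within 1.5 times. A trend on gene span, as labelling or RNA length may give, stays open. With each rat's trend removed, 80.2% and 76.1% of called genes in ET3x2 and ET3x1 were called again in the same direction. The lower, with a jackknife SE of 3.33, lies on the near side of the 80% that would have spoken against it. This measure replaced a count of calls after its value was seen. That count went from 2816 to 2781 genes in ET3x2 and from 2865 to 2802 in ET3x1. Fewer glomeruli in the tissue taken cannot be told apart from a strain difference either: with the glomerulus markers' mean as a covariate the median ratio was 0.618 (jackknife SE 0.158), and calls fell to 9 and 2 as the median standard error rose from 0.0650 to 0.108 in ET3x2 and from 0.0644 to 0.116 in ET3x1. An effect of the congenic segments, which the design names, also stays open and untested. It cannot be told apart from anything else that differed between S and both congenic strains. The labels give no litter or batch, and the S rats carry animal numbers of another series. Hybridisation, as the spike-ins show it, was not weighed for these differences.

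More probe sets were called between the diets in ET3x1 (2457) than in S (430), the ET3x1 count being 1354 without ET3x1 low-salt rat 2, 1353 without ET3x1 low-salt rat 3 and 1511 without ET3x1 high-salt rat 3, and the S count 174 without S low-salt rat 1, 235 without S low-salt rat 2, 871 without S low-salt rat 3, 145 without S low-salt rat 4, 1000 without S low-salt rat 5, 195 without S high-salt rat 1, 156 without S high-salt rat 2 and 268 without S high-salt rat 4. With array weights the counts were 4803 and 1091. RNA integrity cannot be told apart from a larger response: with the Gapdh covariate the median change of the probe sets called in ET3x1 was 0.836 of its size (jackknife SE 0.137), and with the beta-actin covariate 0.919 (jackknife SE 0.175), so that the bounds set at 0.5 and 0.8 were not passed by 2 SE. Calls in ET3x1 went to 6 and 820, as the median standard error rose from 0.101 to 0.158 and 0.136. For the 850 probe sets called for the difference in response from S, the median change was 0.894 of its size (jackknife SE 0.141) with Gapdh and 1.01 (jackknife SE 0.133) with beta-actin. Both lie on the side that speaks against RNA integrity as the whole cause, but neither passes 0.8 by 2 SE. Of the 850, 27 and 586 were called again, with 27 and 932 calls in all, as the median standard error rose from 0.139 to 0.180 and 0.151. What keeps this open is that in ET3x1 the Gapdh ratio differed between diets (0.594 ± 0.0265 on high and 0.877 ± 0.0994 on low salt, SD, n = 4). So did the bioD minus bioC spike-in difference, a sign of hybridisation (3.08 ± 0.150 and 2.54 ± 0.236 on RAE230A, 3.03 ± 0.125 and 2.23 ± 0.168 on RAE230B, SD, n = 4). With it as a covariate the median change of the probe sets called in ET3x1 was 0.935 of its size (jackknife SE 0.0521), past 0.8 by 2 SE. Of these 2457, 897 were called again, as the median standard error rose to 0.126. This does not settle hybridisation within ET3x1, because the slope of the covariate comes from the spread within groups. On RAE230A that spread was largest in S rats on high salt (SD 0.702, n = 5, against 0.113 to 0.236 elsewhere). There rats 1 and 2 had 1.65 and 1.55, and leaving out 1 rat at a time does not remove both. For the difference in response from S hybridisation stays open too, at 0.894 (jackknife SE 0.0744), with 56 of the 850 called again as the median standard error rose to 0.173. A strain difference in the response to salt, which the design names, stays open and untested apart from RNA integrity and hybridisation.

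Rtel1 signal was higher in both congenic strains than in S. The other probe set was higher too, with a moderated statistic of at least 3.73 in either strain. A sequence variant under 1 probe set stays open all the same. Of 15473 tested probe sets 4415 in ET3x2 and 5001 in ET3x1 were called, with a median absolute change of 0.24. The 0.32 and 0.22 of the second probe set were near that size, so its rise cannot be told apart from these widespread differences. A change of the distal list as a whole as large as that of Rtel1 is argued against in both strains. The other 56 genes of the distal list had a median change of 0.0770 (SD 0.151) in ET3x2 and 0.00309 (SD 0.175) in ET3x1, below the 0.32 and 0.22 of the Rtel1 probe set that changed least by over 1 SD. Of the 56, 4 in ET3x2 and 7 in ET3x1 rose by as much or more. A change confined to a smaller stretch around Rtel1 is not covered by this median and was not tested. Smaller changes that are more frequent on the list than elsewhere stay open in both strains, though they would not account for Rtel1. The odds ratio of a call was 0.952 in ET3x2, with a 95% interval of 0.505 to 1.72, and 1.14 in ET3x1, with an interval of 0.626 to 2.02, so that either interval holds values on both sides of 1. A variant may still lie behind the excess of the first probe set, 0.49 or more over the second, which these tables cannot settle. A difference between the strains in Rtel1 transcript, which the design names, also stays open and was not tested apart from these.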

How the results depend on the processing

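The beta-actin and spike-in covariates and the 2 pairs of rats left out were chosen only after the data were seen. Main counts of called probe sets were ET3x2 vs S 4415, ET3x1 vs S 5001, ET3x2 vs ET3x1 1725, salt 2239, salt in S 430, salt in ET3x1 2457, salt in ET3x2 47, response of ET3x1 vs S 850, response of ET3x2 vs S 3, ET3x1 vs S on low salt 4150, ET3x1 vs S on high salt 2246, ET3x2 vs S on low salt 2817 and ET3x2 vs S on high salt 658. All 13 stayed within 1.5 times these without an intensity trend. Counts past that were, without a filter (more probe sets tested), ET3x2 vs S 7702, ET3x1 vs S 9427, ET3x2 vs ET3x1 3055, salt in ET3x2 109, response of ET3x2 vs S 8, ET3x1 vs S on low salt 7187, ET3x1 vs S on high salt 3940 and ET3x2 vs S on low salt 4728, and with the brightest 25% (fewer tested), ET3x2 vs S 2346, ET3x1 vs S 2460, ET3x2 vs ET3x1 790, salt 1359, salt in ET3x1 1353, response of ET3x1 vs S 508, ET3x1 vs S on low salt 2353, ET3x1 vs S on high salt 1005, ET3x2 vs S on low salt 1509 and ET3x2 vs S on high salt 326. In a fit of the compared strains alone (fewer samples) they were salt in S 77, salt in ET3x2 1 and response of ET3x2 vs S 0, with quantile normalization response of ET3x2 vs S 1, with medians centred response of ET3x2 vs S 0, adjusted within each chip salt in ET3x2 113 and with array weights salt 4234, salt in S 1091, salt in ET3x1 4803, salt in ET3x2 1140, response of ET3x1 vs S 2388, response of ET3x2 vs S 416 and ET3x2 vs S on high salt 1319. With the Gapdh covariate they were ET3x2 vs ET3x1 462, salt 25, salt in ET3x1 6, salt in ET3x2 0, response of ET3x1 vs S 27, response of ET3x2 vs S 0, ET3x1 vs S on high salt 227 and ET3x2 vs S on low salt 1542, with beta-actin salt 466, salt in S 174, salt in ET3x1 820, salt in ET3x2 74, response of ET3x2 vs S 10 and ET3x1 vs S on high salt 720, and with the spike-ins ET3x2 vs ET3x1 633, salt in S 137, salt in ET3x1 958, response of ET3x1 vs S 58, response of ET3x2 vs S 0, ET3x1 vs S on high salt 653 and ET3x2 vs S on low salt 1437. Without S low-salt rat 1 and ET3x2 low-salt rat 3 they were salt in S 254, salt in ET3x2 224, response of ET3x2 vs S 0 and ET3x2 vs S on high salt 1005, and without S high-salt rats 1 and 2 salt in S 67, response of ET3x1 vs S 358, ET3x1 vs S on high salt 1279 and ET3x2 vs S on high salt 25. Leaving out 1 rat at a time gave ET3x2 vs S 3376 to 4898, ET3x1 vs S 4122 to 5225, ET3x2 vs ET3x1 842 to 1951, salt 1731 to 2700, salt in S 145 to 1000, salt in ET3x1 1353 to 3328, salt in ET3x2 1 to 294, response of ET3x1 vs S 308 to 1547, response of ET3x2 vs S 0 to 44, ET3x1 vs S on low salt 2448 to 4404, ET3x1 vs S on high salt 1126 to 2440, ET3x2 vs S on low salt 1345 to 3907 and ET3x2 vs S on high salt 79 to 930. Single rats that moved a count past 1.5 times: ET3x2 vs ET3x1 was 842 without ET3x1 low-salt rat 1 and 1047 without ET3x1 high-salt rat 3. Salt in S was 174 without S low-salt rat 1, 235 without S low-salt rat 2, 871 without S low-salt rat 3, 145 without S low-salt rat 4, 1000 without S low-salt rat 5, 195 without S high-salt rat 1, 156 without S high-salt rat 2 and 268 without S high-salt rat 4. Salt in ET3x1 was 1354 without ET3x1 low-salt rat 2, 1353 without ET3x1 low-salt rat 3 and 1511 without ET3x1 high-salt rat 3. Salt in ET3x2 was 73 without S low-salt rat 1, 17 without ET3x2 low-salt rat 2, 149 without ET3x2 low-salt rat 3, 14 without ET3x2 low-salt rat 4, 1 without ET3x2 high-salt rats 1 or 3, 26 without ET3x2 high-salt rat 2 and 294 without ET3x2 high-salt rat 4. Response of ET3x1 vs S was 566 without S low-salt rat 1, 549 without S high-salt rat 2, 1547 without ET3x1 low-salt rat 1, 313 without ET3x1 low-salt rat 2, 308 without ET3x1 low-salt rat 3, 434 without ET3x1 high-salt rat 3 and 479 without ET3x1 high-salt rat 4. Response of ET3x2 vs S was 0 without S low-salt rats 1, 2 or 4, S high-salt rats 2, 3, 4 or 5, ET3x1 high-salt rat 3, ET3x2 low-salt rats 1, 2 or 4 or ET3x2 high-salt rats 1, 2 or 3, 20 without S low-salt rat 3, 43 without ET3x2 low-salt rat 3 and 44 without ET3x2 high-salt rat 4. ET3x1 vs S on low salt was 2448 without ET3x1 low-salt rat 2. ET3x1 vs S on high salt was 1202 without ET3x1 high-salt rat 3 and 1126 without ET3x1 high-salt rat 4. ET3x2 vs S on low salt was 1345 without ET3x2 low-salt rat 1 and 1773 without ET3x2 low-salt rat 2. ET3x2 vs S on high salt was 216 without S high-salt rat 1, 235 without S high-salt rat 2, 293 without S high-salt rat 3, 79 without ET3x2 high-salt rat 2 and 112 without ET3x2 high-salt rat 4. The overlap of both strains' calls was 2329, and 743 with separate S rats (fewer samples), and 1 chromosome stood apart for ET3x2 vs ET3x1 at an adjusted p below 0.2, against 0. Except where a bracket gives it, the cause was not tested. No called change of a named gene reversed under these settings. The change of Sgk1 in ET3x2 vs S, not called in any of them, went from -0.05 to 0.0125 without S high-salt rat 3, 0.00583 without ET3x2 high-salt rat 4, 0.0342 with array weights and 0.0352 with the spike-ins. Of 2860 values with 1 rat left out 2671 kept their side of the threshold, 182 lost and 5 gained a call and 2, those of Sgk1, changed sign, and 48 of 110 lost it with the Gapdh covariate. Dim probe sets below the filter limit what these arrays show.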

Other observations

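The comparison rat by rat was chosen only after the result was seen. Lists not described above gave these results. In ET3x2 against S, blood markers had 2 of 4 higher, the erythroid Alas2 (0.71 ± 0.27) and the platelet Pf4 (0.47 ± 0.09) (camera, adjusted p = 0.241). Interferon and antigen presentation genes had 3 higher and 2 lower of 15, led by the immunoproteasome genes Psmb8 (0.52 ± 0.09) and Psmb9 (0.40 ± 0.11). Of 21 oxidative stress genes 2 rose and 4 fell, led by Gclm (-0.48 ± 0.08) and Cat (-0.47 ± 0.08). Of 22 proximal tubule markers 3 rose and 5 fell, with Gatm (-0.71 ± 0.08), Ggt1 (0.67 ± 0.23) and Lrp2 (-0.52 ± 0.06), Lrp2 being the endocytic receptor megalin. Of 14 collecting duct markers 2 rose and 1 fell, and of 11 of the thick ascending limb and distal tubule 1 and 2. For clock genes the counts were 0 and 3 of 12, for cholesterol synthesis 2 and 3 of 18, for fatty acid oxidation 3 and 1 of 21, for cell division 0 and 3 of 19, for vasoactive genes 4 and 4 of 21 and for glucocorticoid-responsive genes 3 and 3 of 13. For heat shock genes they were 2 and 1 of 14, for water handling 1 and 1 of 13, and for fat, skeletal muscle and ureter markers 1 and 1 of 3, and the 1 adrenal marker was not called. By camera none of these lists was called in ET3x2 against S, the lowest adjusted p being 0.0953 for the thick ascending limb and distal tubule.

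Within strains, 9 of 18 cholesterol synthesis genes were higher and 0 lower on high salt in S rats, led by Idi1 (0.87 ± 0.15) and Cyp51 (0.79 ± 0.17) (camera, adjusted p = 8.7e-10, and adjusted p = 0.184 with an estimated correlation). In ET3x1 the counts were 7 and 1, led by Sqle (0.83 ± 0.11) and Idi1 (0.80 ± 0.16) (camera, adjusted p = 8.2e-05, and adjusted p = 0.517 with an estimated correlation). In ET3x2 they were 2 and 0, Idi1 (0.77 ± 0.16) and Sqle (0.54 ± 0.11) (camera, adjusted p = 7.0e-06, and adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone, the counts were 12 and 0, 8 and 1 and 5 and 0. Injury, matrix and fibrosis genes gave 7 and 0 of 19 in S, 4 and 1 in ET3x1 and 1 and 0 in ET3x2 (camera, adjusted p = 2.5e-07, 0.00301 and 1.5e-04, and adjusted p = 0.212, 0.552 and 0.298 with an estimated correlation). Cell division genes gave 1 and 0 of 19, 4 and 0 and 1 and 0 (camera, adjusted p = 1.9e-04, 4.3e-05 and 1.6e-05, and adjusted p = 0.788, 0.517 and 0.298 with an estimated correlation). By camera no list differed between strains in its response to salt, with lowest adjusted p = 0.429 for ET3x1 and 0.259 for ET3x2.

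Other splits of the same rats into groups of the same sizes were fitted in the same way. For 10 comparisons 1 of 100 splits, the real one, gave as many calls, a share under 0.05 that was not adjusted over the comparisons. This makes chance unlikely for these counts without excluding it: ET3x2 vs S 4415 (highest other 815), ET3x1 vs S 5001 (highest other 65), ET3x2 vs ET3x1 1725 (highest other 647), salt 2239 (highest other 318), salt in S 430 (highest other 383), response of ET3x1 vs S 850 (highest other 275), ET3x1 vs S on low salt 4150 (highest other 3232), ET3x1 vs S on high salt 2246 (highest other 781), ET3x2 vs S on low salt 2817 (highest other 2757) and ET3x2 vs S on high salt 658 (highest other 548). Leaving out 1 rat took 4 of these counts below the highest other split: salt in S to 145, ET3x1 vs S on low salt to 2448, ET3x2 vs S on low salt to 1345 and ET3x2 vs S on high salt to 79. For these chance is unlikely with all rats only, and the other splits were not repeated with a rat left out. For salt in ET3x1 it was 1 of 35, 2457 against 1047, the smallest share that 35 splits can give, which makes chance unlikely too. For salt in ET3x2 2 of 35 splits gave 47 or more, the highest other 563, and chance is not excluded. For the response of ET3x2 vs S 4 of 100 sampled splits gave 3 or more, a share under 0.05, but the highest other was 1049 and the real count was 0 without any 1 of 14 rats and with medians centred, so that chance is not firmly excluded for it. Splits that call several times the real count, as with 1049 and 563, point to a structure of the samples, and what that structure is was not tested.

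Compared rat by rat, 77 probe sets were higher in every ET3x2 rat than in every S rat and 103 lower, where chance gives 0.00457% of probe sets. In ET3x1 they were 168 and 157, and 8 and 39 in both strains. At an adjusted p below 0.2, chromosome 17 stood apart for ET3x2 against ET3x1, with 38.2% of its genes called against 29.0% elsewhere (Fisher's exact test, adjusted p = 0.0468). It did not at the main limit of 0.05 (11.8% against 10.1%, Fisher's exact test, adjusted p = 0.930). Nor did it below 0.01 (2.85% against 2.55%, Fisher's exact test, adjusted p = 0.944). Each adjustment ran over the chromosomes of 1 comparison at 1 limit only.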
